A study of Mus musculus with 71 samples.

How the data were processed

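Bulk RNA sequencing was performed on brain tissue of C57BL/6J mice that had received a burn, an excision or a sham procedure. The burn was made with a heated brass rod 19 mm across, held against the flank for 10 s at over 90 °C, which per the labels gave a full-thickness injury over 7 to 8% of the body surface. Excision removed full-thickness skin over a template 12 mm across, and sham animals were shaved without injury. The burn lay on the right flank, while excision and sham procedures were made on the back. All groups received buprenorphine at 0.1 mg/kg, and paracetamol at 1 mg/mL was given in the drinking water for 5 days. The libraries were read as single-end runs of 100 bp. The time between injury and tissue collection, and whether the regions came from the same animals, are not given in the labels used here.

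The deposited values are counts per gene and library, made by the authors, in a single table of 71 libraries and 55416 Ensembl gene identifiers. All values were whole numbers, and 0 lines held anything other than a gene. The submitters' processing notes name FastQC 0.11.3, fastp, STAR, DESeq2 1.24.0 and the mouse genome build GRCm38. The program that counted reads, the annotation release and the strand setting are not given in the sources used here. Symbols and positions were taken from GENCODE mouse release M21, which matched 52083 identifiers, and the 3333 identifiers without a match held 0.847% of all counts. Reads from near-identical gene copies, such as the Hist1h2b genes and nuclear copies of mitochondrial genes, were counted by rules that are not given in the sources used here.

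Libraries were grouped by the treatment field of their labels. In 4 libraries the title names another treatment than that field, and the treatment field was kept for all of them. Titles of the piriform cortex libraries name the frontal cortex, while their tissue and source fields name the piriform cortex, and the tissue field was used. Total counts ran from 6.65 to 87.8 M (mega, counts) per library, with a median of 57 M. All 270 pairs of libraries within a group were compared, with 0 identical pairs and a lowest chi-square per degree of freedom of 4.78, so that libraries of a group differed by more than counting error. Errors are given as SD over libraries or SE of the fit.

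Each region was fitted separately with edgeR 4.0.16 (TMM normalisation, filterByExpr on the treatment groups, quasi-likelihood F test) under R 4.3.3, with batch as an additive term in the hippocampus and frontal cortex. The 3 contrasts were burn against sham, excision against sham and burn against excision. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no threshold on fold change. Log2 fold changes come from these fits, and levels are given as CPM from edgeR (mean ± SD over libraries). A gene named in the text was required to be called, to have a mean of at least 1 CPM, the same sign in both batches and an assigned symbol. From these the 10 largest changes in each direction were taken, with at most 5 called members of each gene list by smallest p. Where fewer than 5 genes passed, the 10 genes with the smallest p were taken as values and not as calls. Gfap, Aif1, C4b, Bdnf, Fkbp5, Fos, Mbp, Cldn5, Ttr and Hbb-bs were read in every contrast. Genes named outside this rule are said to be so.

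A set of 35 gene lists of 12 to 28 members, covering cell types, neighbouring brain areas, stress responses and signalling, was tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists within each contrast. A list needed 5 members past the count filter, and the test was repeated with the correlation estimated from the data. The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. Differences of the burn effect between regions and between batches were tested as interaction terms in edgeR. Agreement between batches was the correlation across genes of log2 fold changes, and genes are not independent replicates. These were differences of group mean log2 CPM within each batch, after filtering and TMM normalisation over the region. The shared sham group was handled by simulating unchanged groups against it.

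The alternatives were DESeq2 size factors, no count filter, the DESeq2 1.42.0 Wald test, 2 surrogate variables from sva 3.50.0, the replicate number as a block, no batch term, each batch alone, the libraries with disagreeing labels left out, the treatment taken from titles, and each library left out in turn. The replicate block also left out the libraries with disagreeing labels. A pair of alternatives was added after the data were seen: the share of counts in TEC gene models as a covariate, and the hippocampus without the 4 libraries under 10 M counts. TEC models are a class of mostly unspliced transcripts that GENCODE holds as awaiting experimental proof. The pipeline was tested on simulated data with 50 genes changed at each of 4 folds. Of genes changed by 1.5-fold, 84% were recovered in the hippocampus design, 62% in the frontal cortex and 54% in the piriform cortex. For 1.25-fold changes the recovered shares were 36%, 12% and 8%, and false calls made up 6.59%, 5.19% and 4.69% of all calls in the same order.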

Results

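Gene expression was measured in 71 libraries from 3 brain regions of mice, to examine transcriptomic changes in the brain after a non-severe burn. The hippocampus was represented by 10 burn, 10 excision and 9 sham libraries in 2 batches, and the frontal cortex by 10 burn, 10 excision and 8 sham libraries in 2 batches. The piriform cortex came from 1 batch, with 5 burn, 4 excision and 5 sham libraries. Sham libraries were the fewest in batch 2 of the frontal cortex (n = 3) and in batch 1 of the hippocampus (n = 4). Total counts ran from 6.65 to 34.1 M in hippocampus batch 1 and 30.7 to 70.7 M in hippocampus batch 2. They ran from 47.4 to 87.8 M and 53.3 to 86.6 M in the frontal cortex batches and from 46.8 to 76.4 M in the piriform cortex. The 4 libraries under 10 M counts were hippocampus burn replicate 5, excision replicates 3 and 5 and sham replicate 1, all of batch 1.

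The labels of 4 libraries disagree with themselves. Frontal cortex burn replicates 7 and 8 carry titles that name sham, frontal cortex excision replicate 7 has a title that names burn, and piriform cortex sham replicate 2 has a title that names excision. By values read after the data were seen, Hspa5 was at 218 and 205 CPM in frontal cortex burn replicates 7 and 8 and at 343 CPM in excision replicate 7. The other burn libraries of that batch held 171 to 201 CPM, the other excision libraries 262 to 294 CPM and the sham libraries 306 to 341 CPM. Creld2 was at 11.2 and 14.3 CPM in those burn libraries (other burn 11.9 to 17.5 CPM, sham 17.8 to 19.6 CPM) and at 21.6 CPM in excision replicate 7. Plin4 was at 12.2 and 3.29 CPM in burn replicates 7 and 8 (other burn 13.7 to 20.4 CPM, sham 1.96 to 5.91 CPM) and at 9.81 CPM in excision replicate 7 (other excision 10.4 to 12.5 CPM). These values lay on the side of the treatment field except Plin4 in burn replicate 8, which lay with sham, and Hspa5 and Creld2 were called under that field. The library names also hold a running number. By the treatment field these numbers fall in the same runs of treatment in frontal cortex batch 2 as in hippocampus batch 2. Titles would place burn replicates 7 and 8 as sham within the burn run. In the piriform cortex the treatment field gives the runs of hippocampus batch 1. The library names thus side with the treatment field for all 4 libraries. Within each batch the numbers run through whole treatments: excision, sham, then burn in batch 1 and in the piriform cortex, and burn, excision, then sham in batch 2. Whether they follow an order of collection or processing is not given, so treatment cannot be separated from such an order. Mitochondrial transcripts took 1.98 to 8.59% of counts in the frontal cortex batch 1 libraries and 3.47 to 10.4% in the piriform cortex, so this share varied several-fold within batches.

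The hippocampus after burn was compared with sham to ask which transcripts an injury of the skin moves in this region. Some genes of protein folding in the endoplasmic reticulum (ER) fell. Creld2, an ER protein induced by ER stress (ENSMUSG00000023272, GRCm38 chromosome 15, 88819646 to 88826683), was at 20.8 ± 2.79 CPM in sham (SD, n = 9) and 14.9 ± 2.6 CPM in burn (SD, n = 10), a log2 fold change of -0.52 (SE 0.08, adjusted p = 0.00162). Sdf2l1, a component of an ER chaperone complex, fell by 0.60 on the log2 scale (SE 0.11, adjusted p = 0.00906), and Manf, a secreted factor induced by ER stress, fell by 0.40 (SE 0.08, adjusted p = 0.0111). The protein disulfide isomerase Pdia6 and Xbp1, a transcription factor of the unfolded protein response, fell by 0.31 (SE 0.06) and 0.34 (SE 0.07), each with adjusted p = 0.0146. Hspa5, which encodes the ER chaperone BiP, fell by 0.41 (SE 0.09, adjusted p = 0.0211) and Pdia4 by 0.35 (SE 0.09, adjusted p = 0.0482). These were the 7 called members of the 20 in the heat shock and unfolded protein response list, of which 14 passed when adjusted over the list alone. The list's camera adjusted p was 6.4e-11. With an estimated correlation its adjusted p was 0.31. The 7 members had a median log2 fold change of -0.16 in batch 1 alone, where 1 was called, and -0.54 in batch 2 alone, where 7 were called.

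**Figure D1:**
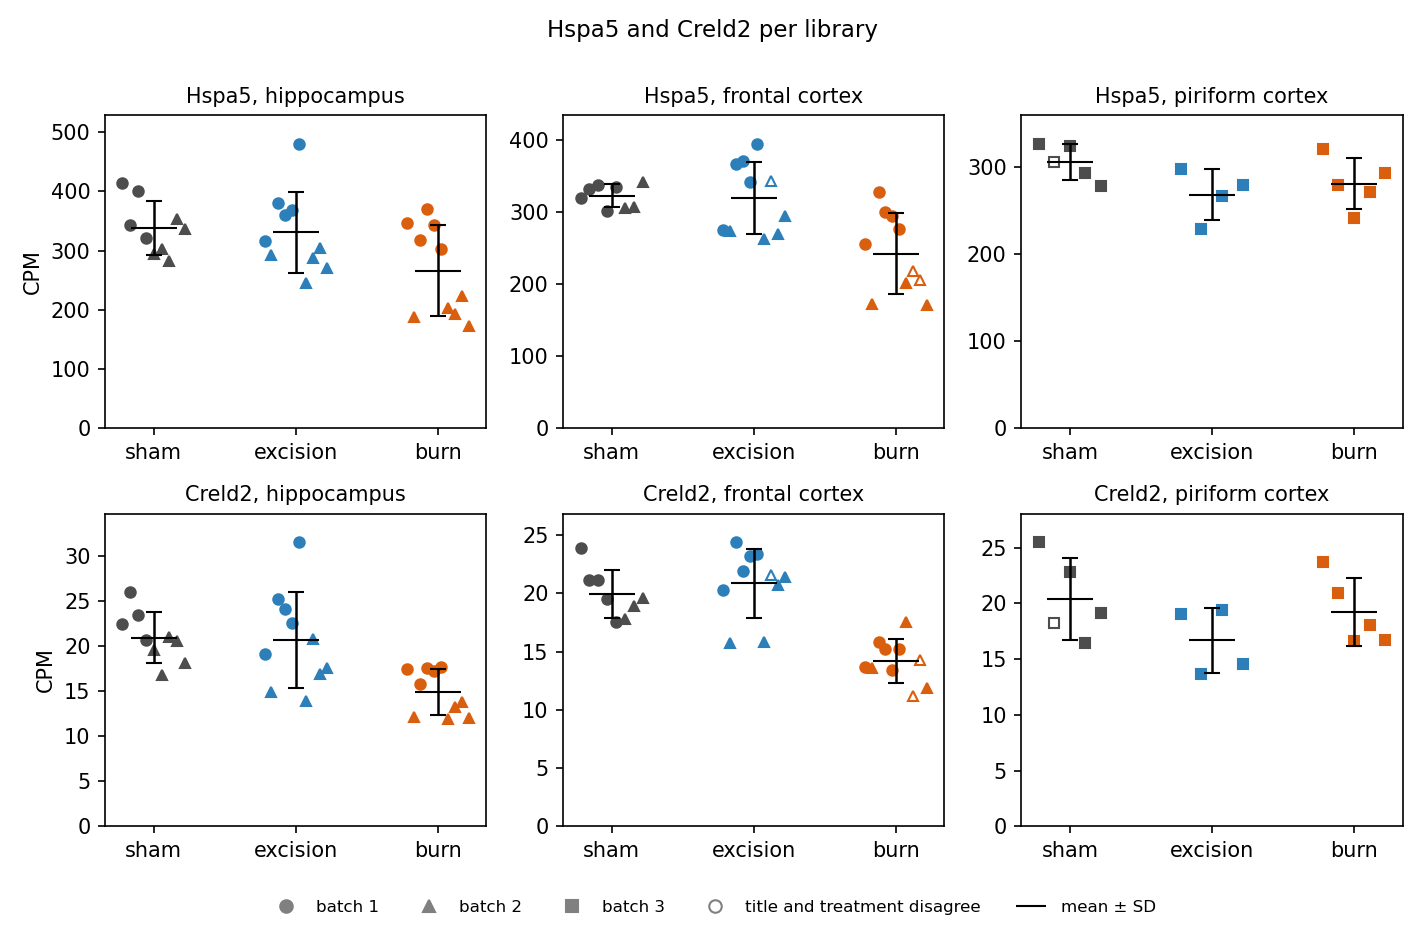
Levels of Hspa5 and Creld2 in CPM (y axis, from 0) for each library, by treatment (x axis) in the 3 regions; each point is 1 library, marker shape gives the batch, open markers are libraries whose labels disagree, and bars show the mean ± SD. In hippocampus batch 2, Creld2 lay between 11.9 and 13.8 CPM in burn and between 16.8 and 21 CPM in sham.

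Single genes of other groups were called in the hippocampus after burn. Dbp, a transcription factor of the circadian clock output, rose from 31.5 ± 10.9 to 44.5 ± 2.52 CPM, with a log2 fold change of 0.56 (SE 0.11, adjusted p = 0.0146) that was 0.02 in batch 1 and 1.00 in batch 2. It was the called member of the clock list's 15 measured genes, of which 2 passed as higher and 1 as lower when adjusted over the list alone, and the list was not called (median 0.03, camera adjusted p = 0.65). Stat2 and Irf9, transcription factors of interferon signalling, fell by 0.34 (SE 0.08, adjusted p = 0.0336) and 0.51 (SE 0.12, adjusted p = 0.0348). They were the 2 called of 19 interferon genes and the 2 passing over the list alone, and the list was not called (median -0.11, camera adjusted p = 0.072). Htr7, a serotonin receptor, rose by 0.41 (SE 0.10, adjusted p = 0.0357) and Maoa, which encodes monoamine oxidase A, rose by 0.25 (SE 0.06, adjusted p = 0.0336). These were the 2 called among the 18 members of the monoamine and opioid list, with 3 adjusted over the list alone. That list had a camera adjusted p of 0.029. Its adjusted p was 0.91 with an estimated correlation. Fosb, an activity-induced transcription factor, fell by 0.60 (SE 0.15, adjusted p = 0.039) and was the called member of the 17 immediate early genes, 1 of which passed adjusted over the list alone, with a camera adjusted p of 0.037 and adjusted p = 0.91 with an estimated correlation. The median of that list was -0.25, and it reversed to 0.05 in batch 1 alone. Insig1, an ER protein that restrains cholesterol synthesis, rose by 0.25 (SE 0.05, adjusted p = 0.0217), 2 genes of its list passed adjusted over the list alone, and the list was not called (median 0.04, camera adjusted p = 0.33). The astrocyte list stood higher in 14 of 15 genes with 0 called and 0 adjusted over the list alone, a median of 0.10 and a camera adjusted p of 0.034, and adjusted p = 0.91 with an estimated correlation.

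In all, edgeR called 202 of 19574 genes in hippocampus burn against sham, 57 higher and 145 lower, with 3470 at an unadjusted p under 0.05 where 979 would come by chance, and 200 of the 202 had the same sign in both batches. Genes were called from both batches together, so a shared sign was partly fixed by that selection, here and in the contrasts below. The changes were small, and 50 of the called genes passed 1.5-fold. The largest rises were those of Dgkk, a diacylglycerol kinase, at 1.08 (SE 0.26), the ligand Wnt9a at 0.73 (SE 0.14), Efhc2 at 0.71 and the ferroxidase Heph at 0.61, followed by Dbp, Map3k21, the potassium channel Kcna4, Trmt9b, Tox and Klf11 at 0.46 to 0.56. The largest falls were those of the metalloprotease Adam8 at -1.34 (SE 0.31), Crip3 at -1.32 (SE 0.32) and the immune adaptor Dok3 at -1.26 (SE 0.26), followed by Noxred1, the complement factor properdin (Cfp), Ssc5d, Ifi203, the helicase Recql4, Shkbp1 and Fndc8 at -1.17 to -1. Adam8 lay at -2.33 in batch 1 and -0.69 in batch 2, and Cfp at -2.02 and -0.52. Batch 1 includes sham replicate 3, a library with neutrophil transcripts described below, and its part in the falls of that batch is not given here. Batch 2 does not hold that library, and Adam8 and Cfp were lower there too. Counts in TEC gene models differed in the same batch, at 0.0498 ± 0.00509% in burn (SD, n = 5) and 0.0694 ± 0.0144% in sham (SD, n = 4) of batch 1, against 0.07 ± 0.0076% and 0.0704 ± 0.00473% in batch 2 (n = 5 each). With that share as a covariate, chosen after the data were seen, 30 genes were called, 26 of them among the 202, and all 145 lower genes kept their sign. Batch 2 alone gave 31 calls, batch 1 alone 1324, 2 surrogate variables 83, a replicate block 169, a fit without a batch term 106 and no count filter 123, while DESeq2 called 629 that held all 202. Leaving out 1 library gave from 50 calls, without sham replicate 5, to 745, without burn replicate 8.

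Of the genes read in every contrast, none was called in hippocampus burn against sham. The astrocyte gene Gfap was at 343 ± 54.9 CPM in sham and 359 ± 46 CPM in burn (log2 fold change 0.05, SE 0.09, adjusted p = 0.812), and the microglial gene Aif1 was at -0.16 (SE 0.13, adjusted p = 0.544). The log2 fold changes of C4b, Bdnf, Fkbp5, Fos, Mbp and Cldn5 ran from -0.40 to 0.18, with adjusted p from 0.411 to 0.918. Ttr, the main transcript of the choroid plexus, varied from library to library, at 1030 ± 1760 CPM in sham and 1860 ± 2070 CPM in burn, and all 17 genes of the choroid plexus and ependyma list stood higher in burn with 0 called, at a median of 0.84 and a camera adjusted p of 0.092. The cytokine and NF-kB list had a median of -0.03 over 13 measured genes (camera adjusted p = 0.68), and the reactive astrocyte list -0.04 over 15 (camera adjusted p = 0.38), with 0 members called in each.

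Burn was then compared with excision in the hippocampus, which sets the burn beside another full-thickness skin injury. The injuries also differed in size and site, with a 19 mm rod on the flank and a 12 mm template on the back. The kind of injury is thus not separated from its size or site, here and in the other regions. Of the 7 ER genes above, 4 were called here too, with Creld2 at 20.7 ± 5.49 CPM in excision and 14.9 ± 2.6 CPM in burn (n = 10 each; log2 fold change -0.45, SE 0.08, adjusted p = 0.00702). Xbp1 fell by 0.37 (SE 0.07, adjusted p = 0.0149), Sdf2l1 by 0.55 (SE 0.11, adjusted p = 0.0196) and Manf by 0.35 (SE 0.07, adjusted p = 0.0381), which gave 4 called of 20 members and 14 adjusted over the list alone. Hspa5 (-0.34, adjusted p = 0.0751), Pdia4 (-0.36, adjusted p = 0.0658) and Pdia6 (-0.22, adjusted p = 0.0951) were not called. The list's camera adjusted p was 3e-11. An estimated correlation gave an adjusted p of 0.28. Banp, a nuclear DNA-binding protein, fell by 0.61 (SE 0.09, adjusted p = 0.0017), and the zinc finger gene Zbtb40 also by 0.61 (SE 0.09, adjusted p = 0.00261). Xdh, which encodes xanthine dehydrogenase, was at 2.25 ± 0.728 CPM in burn and 3.97 ± 1.14 CPM in excision (log2 fold change -0.80, SE 0.15), against 2.52 ± 0.529 CPM in sham. Sox18, an endothelial transcription factor, fell by 0.56 (SE 0.09, adjusted p = 0.00473), and Cys1, Ablim3, Nfya and St5 lay between -0.51 and -0.40. The largest rise was that of Fam181a, at 0.90 (SE 0.16, adjusted p = 0.0139), and Map3k21, Zbtb11os1, Galk1, Sat2, Zfp46, Nim1k, Idh2, Bloc1s5 and Phf13 rose by 0.26 to 0.56.

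Lists other than that of the ER genes had 0 called members in hippocampus burn against excision, and their camera calls were lost with an estimated correlation. Oxidative phosphorylation genes stood higher in 24 of 24, with 0 adjusted over the list alone (median 0.12, camera adjusted p = 5.9e-07, and adjusted p = 0.71 with an estimated correlation). Ribosomal protein genes stood higher in 28 of 28, with 0 adjusted over the list alone (median 0.12, camera adjusted p = 0.00019, and adjusted p = 0.71 with an estimated correlation). The endothelial and blood-brain barrier list was lower in 14 of 16 genes (median -0.25, 3 lower adjusted over the list alone, camera adjusted p = 0.00024). The adjusted p was 0.71 where the correlation was estimated. Against sham the endothelial median was 0.04 after burn (11 of 16 higher, camera adjusted p = 0.62) and 0.24 after excision. This difference thus lay mostly on the side of excision. The interferon list was lower in 17 of 19 genes, with 2 adjusted over the list alone (median -0.24, camera adjusted p = 0.006). Estimating the correlation moved its adjusted p to 0.71. The neurogenesis list was lower in 13 of 14 genes, with 0 adjusted over the list alone (median -0.21, camera adjusted p = 0.0037). With an estimated correlation its adjusted p was 0.35. Choroid plexus genes stood higher in 17 of 17, with 0 adjusted over the list alone (median 0.99, camera adjusted p = 0.0013). Its adjusted p was 0.71 with an estimated correlation. In this contrast 41 genes were called, 13 higher and 28 lower, with 2790 at an unadjusted p under 0.05, and 40 kept their sign in both batches. No gene was called by edgeR in batch 2 alone, where 1446 had an unadjusted p under 0.05, and Zbtb40, Banp and Sox18 were the 3 called without the 4 shallow libraries. In the same contrast batch 1 alone gave 197, no count filter 21, 2 surrogate variables 18, a replicate block 21, no batch term 8, the TEC covariate 19 and DESeq2 303. Leaving out 1 library gave from 9 calls, without excision replicate 5, to 326, without burn replicate 8. None of the genes read in every contrast was called, the smallest adjusted p among them being 0.326 for Cldn5 (log2 fold change -0.32, SE 0.15).

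Excision against sham in the hippocampus gave 0 called genes by edgeR and 0 by DESeq2, with 727 of 19574 at an unadjusted p under 0.05 where 979 would come by chance. The smallest p were those of Xdh, at 3.97 ± 1.14 CPM in excision (n = 10) and 2.52 ± 0.529 CPM in sham (n = 9; log2 fold change 0.64, SE 0.16, adjusted p = 0.852), Adgrl4 (0.55) and Asnsd1 (-0.42). The endothelial adhesion gene Pecam1 was at 0.45 (SE 0.13, adjusted p = 0.852), and Igkc, an immunoglobulin light chain, at -2.84 (SE 0.81) with 2.72 ± 7.31 CPM in sham. Oxidative phosphorylation genes stood lower in 20 of 24, with 0 adjusted over the list alone (median -0.11, camera adjusted p = 0.00028), and ribosomal protein genes in 28 of 28, with 0 adjusted over the list alone (median -0.08, camera adjusted p = 0.0016), each at adjusted p = 0.98 with an estimated correlation. In burn against sham their medians were 0.02 and 0.04 (camera adjusted p = 0.11 and 0.33), so their difference between burn and excision lay mostly on the side of excision. Hhex, Sema3g, B3gnt2, Xk and Myo1f lay between -0.31 and 0.54, and the genes read in every contrast had adjusted p of 0.852 to 0.991. All 16 endothelial genes stood higher, 1 of them adjusted over the list alone (median 0.24, camera adjusted p = 2e-09). An estimated correlation gave an adjusted p of 0.33. The clock list was higher in 13 of 15 genes, with 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.0016). The adjusted p was 0.64 where the correlation was estimated.

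The same comparison of burn with sham in the frontal cortex again had ER chaperones among the lower genes. Hspa5 (ENSMUSG00000026864, GRCm38 chromosome 2, 34771970 to 34777547) was at 324 ± 15.8 CPM in sham (SD, n = 8) and 240 ± 51.6 CPM in burn (SD, n = 10), a log2 fold change of -0.42 (SE 0.08, adjusted p = 0.0203). Pdia4 fell by 0.45 (SE 0.07, adjusted p = 0.00403), Creld2 by 0.49 (SE 0.09, adjusted p = 0.00998), Xbp1 by 0.33 (SE 0.06, adjusted p = 0.0203) and Sdf2l1 by 0.54 (SE 0.12, adjusted p = 0.0406). These 5 of 20 members were called, and 10 passed adjusted over the list alone. The list's camera adjusted p was 1.6e-08, and estimating the correlation moved its adjusted p to 0.26. The called members had a median of -0.30 in batch 1 alone, where 2 were called, and -0.55 in batch 2 alone, where 0 were called by edgeR. Serpinh1, the chaperone of collagen, fell by 0.55 (SE 0.13, adjusted p = 0.0495), Sparc, a matrix protein, by 0.43 (SE 0.09, adjusted p = 0.0404) and Gpr17, a receptor of oligodendrocyte precursors, by 0.38 (SE 0.08, adjusted p = 0.0399). Gpr17 was the called member of the 13 in its list, 1 of which passed adjusted over the list alone (median -0.14, camera adjusted p = 0.021). With an estimated correlation its adjusted p was 0.64.

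Transcripts that rose in the frontal cortex after burn included Usp43, a ubiquitin peptidase, from 1.87 ± 0.516 to 4.5 ± 1.18 CPM (log2 fold change 1.25, SE 0.23, adjusted p = 0.0153). The kinase Map3k21 rose by 1.13 (SE 0.18, adjusted p = 0.00632), the phospholipase Pla2g4e by 0.90 (SE 0.18) and Wnt9a by 0.74 (SE 0.15). Ninl, Tox and the kinases Hunk and Pak7 rose by 0.58 to 0.63, and Mansc1 by 0.58. Lower genes were Map3k19 at -0.64, the histone genes Hist1h2bp, Hist1h2bl, Hist1h2bq and Hist1h2br at -0.60 to -0.59, which are near-identical copies, and Zhx2 at -0.51, Zbtb40 at -0.49 and Banp at -0.49. All 15 astrocyte genes stood lower with 0 called and 4 adjusted over the list alone (median -0.22, camera adjusted p = 3.8e-05). Its adjusted p was 0.56 with an estimated correlation. Microglial genes were lower in 15 of 16, with 2 adjusted over the list alone (median -0.18, camera adjusted p = 0.001). An estimated correlation gave an adjusted p of 0.62. Genes of the thalamus, hypothalamus and septum, areas outside the frontal cortex, stood lower in 14 of 15, with 0 adjusted over the list alone (median -0.38, camera adjusted p = 0.006). The adjusted p was 0.56 where the correlation was estimated.

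In frontal cortex burn against sham 59 of 21077 genes were called, 34 higher and 25 lower, with 2741 at an unadjusted p under 0.05 and 58 of the same sign in both batches. None of the genes read in every contrast was called, with adjusted p from 0.358 for Bdnf (log2 fold change 0.24, SE 0.11) to 0.721 for Mbp, and Gfap at -0.33 (SE 0.17, adjusted p = 0.412). The call count depended on the disputed labels, for which the library names side with the treatment field. Without the frontal cortex libraries whose labels disagree, 32 genes were called, 29 of them among the 59, and with treatment taken from titles edgeR called 0, with 2098 at an unadjusted p under 0.05. A replicate block, which also left those libraries out, gave 0 by edgeR with 2176 at an unadjusted p under 0.05, and batch 2 alone gave 0 with 1178. Batch 1 alone gave 1328, no batch term 26 and no count filter 24, while DESeq2 called 328, 2 surrogate variables gave 288 and the TEC covariate 153. With 1 library left out the calls ran from 19, without sham replicate 8, to 206, without burn replicate 6.

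Burn against excision in the frontal cortex also had lower ER genes. Pdia4 was at 46.4 ± 6.61 CPM in excision and 33.1 ± 5.56 CPM in burn (SD, n = 10 each; log2 fold change -0.49, SE 0.06, adjusted p = 0.000334), and Creld2 fell by 0.56 (SE 0.08, adjusted p = 0.00079). Xbp1 fell by 0.41 (SE 0.06, adjusted p = 0.00151), Sdf2l1 by 0.72 (SE 0.11, adjusted p = 0.00161) and Hspa5 by 0.43 (SE 0.08, adjusted p = 0.0123). With Pdia6 (-0.37, SE 0.07, adjusted p = 0.0236) 6 of the 20 members were called and 12 adjusted over the list alone. The list passed camera with an adjusted p of 8.1e-18, and held at adjusted p = 0.01 with an estimated correlation. Banp fell by 0.66 (SE 0.09, adjusted p = 0.00079), Zhx2 by 0.49 and Zbtb40 by 0.52, Plekhg4 by 1.23 (SE 0.24), Serinc2 by 0.85, Sfn by 0.67 and the corepressor Cbfa2t3 by 0.58. Hunk rose by 0.64 (SE 0.11, adjusted p = 0.00728), Tipin, a replication fork protein, by 0.42 (SE 0.07, adjusted p = 0.00161), and Slitrk1, a neuronal adhesion protein, by 0.48 (SE 0.10, adjusted p = 0.0331), and Ninl, Tnfrsf11a, Prr16, Sh2d3c, Mansc1, Lactb2 and Mfsd4a by 0.39 to 0.57.

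In the same contrast all 13 genes of striatal projection neurons, markers of a neighbouring area, stood lower in burn than in excision, with 0 called and 0 adjusted over the list alone (median -0.56, camera adjusted p = 0.013). Estimating the correlation moved its adjusted p to 0.97. In all 44 genes were called, 17 higher and 27 lower, with 2442 at an unadjusted p under 0.05 and 44 of the same sign in both batches. None of the genes read in every contrast was called, the smallest adjusted p being 0.367 for Fkbp5 (log2 fold change -0.24, SE 0.10). Without the libraries with disagreeing labels 15 genes were called and with treatment from titles 1, which was Tipin. A replicate block left 8 genes, batch 2 alone 0 by edgeR with 490 at an unadjusted p under 0.05, and no count filter 12, while batch 1 alone gave 1318, DESeq2 175 and 2 surrogate variables 173. With 1 library left out the calls ran from 10, without burn replicate 3, to 284, without burn replicate 6.

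In the frontal cortex excision against sham gave 0 called genes by edgeR and 0 by DESeq2, with 1007 at an unadjusted p under 0.05 where 1054 would come by chance. Astrocyte genes stood lower in 15 of 15, with 0 called and 7 adjusted over the list alone (median -0.27, camera adjusted p = 7.9e-13). With an estimated correlation its adjusted p was 0.08. Among them Mlc1 was at 194 ± 34.4 CPM in sham (SD, n = 8) and 153 ± 14.1 CPM in excision (SD, n = 10; log2 fold change -0.33, SE 0.08, adjusted p = 0.806). Sparc was at -0.39 (SE 0.09, adjusted p = 0.806), B3gnt8 at 0.75 (SE 0.18, adjusted p = 0.806), and Dcxr, Itih3, Tril, Suclg2, Mettl27, Phka1 and Tmem100 lay between -0.51 and 0.44. The genes read in every contrast had adjusted p of 0.951 to 0.997. The heat shock and unfolded protein response list stood higher in 17 of 20 genes, with 0 adjusted over the list alone (median 0.07, camera adjusted p = 0.011, and adjusted p = 0.60 with an estimated correlation), which adds to its difference between burn and excision. All 13 oligodendrocyte precursor genes stood lower, with 0 adjusted over the list alone (median -0.15, camera adjusted p = 0.00019, and adjusted p = 0.31 with an estimated correlation), as did 17 of 19 matrix and perineuronal net genes, with 2 adjusted over the list alone (median -0.18, camera adjusted p = 0.00021). Its adjusted p was 0.31 with an estimated correlation.

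In the piriform cortex no gene was called in any contrast by edgeR, and the list with the smallest camera p in burn against excision was that of glucocorticoid response genes. In burn against excision 16 of the 18 genes of that list stood higher, with 0 called and 12 adjusted over the list alone (median 0.63, camera adjusted p = 2e-10). An estimated correlation gave an adjusted p of 0.09. Plin4, a coat protein of lipid droplets, was at 2.54 ± 1.34 CPM in excision (SD, n = 4), 7.41 ± 4.24 CPM in sham (SD, n = 5) and 22.6 ± 7.89 CPM in burn (SD, n = 5), a log2 fold change of 3.16 (SE 0.49, adjusted p = 0.155). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was at 0.77 (SE 0.14, adjusted p = 0.294), and Fkbp5, a chaperone of the glucocorticoid receptor, at 0.74 (SE 0.20, adjusted p = 0.417). Immediate early genes went the other way in 16 of 17, with 0 called and 11 adjusted over the list alone (median -0.57, camera adjusted p = 2.2e-09). The adjusted p was 0.45 where the correlation was estimated. Fos was at 42.4 ± 18.5 CPM in excision, 23.2 ± 8.26 CPM in sham and 20.1 ± 2.78 CPM in burn, with a log2 fold change of -1.08 (SE 0.28, adjusted p = 0.394). Smim3, Dpysl3, Phf13, Ak4, Ky, Gpr19, Col6a4 and Inhba were the other genes of smallest p, with adjusted p of 0.294.

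The piriform contrast of burn with excision had 1658 of 21004 genes at an unadjusted p under 0.05 where 1050 would come by chance, and DESeq2 called 59. Microglial genes stood lower in 16 of 16, with 0 adjusted over the list alone (median -0.16, camera adjusted p = 0.00011, and adjusted p = 0.52 with an estimated correlation). Myelin genes stood higher in 15 of 16, with 0 adjusted over the list alone (median 0.30, camera adjusted p = 0.0035), and endothelial genes in 13 of 16, with 2 adjusted over the list alone (median 0.26, camera adjusted p = 0.0042), each at adjusted p = 0.74 with an estimated correlation. All 13 striatal genes stood higher in burn, with 0 adjusted over the list alone (median 0.75, camera adjusted p = 0.0065, and adjusted p = 0.79 with an estimated correlation), and 14 of 16 choroid plexus genes lower, with 0 adjusted over the list alone (median -0.86, camera adjusted p = 0.0035). Estimating the correlation moved its adjusted p to 0.74. Plin4 was the 1 gene called by edgeR with no count filter, with a replicate block and with treatment from titles.

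Burn against sham in the piriform cortex had 0 called genes by edgeR, 896 at an unadjusted p under 0.05 and 1 called by DESeq2 (Cdc42ep4). The ER genes were not called here, with Pdia6 at -0.21 (SE 0.09), Manf at -0.20 (SE 0.10), Sdf2l1 at -0.15 (SE 0.14), Hspa5 at -0.12 (SE 0.09) and Creld2 at -0.09 (SE 0.14), at adjusted p of 0.884 to 0.927. The heat shock and unfolded protein response list was lower in 18 of 20 genes, with 1 adjusted over the list alone (median -0.17, camera adjusted p = 2e-06). With an estimated correlation its adjusted p was 0.69. The stress-induced transcription factor Atf3 was its lowest member, at 1.62 ± 0.601 CPM in sham and 0.666 ± 0.245 CPM in burn (SD, n = 5 each; log2 fold change -1.29, SE 0.31, adjusted p = 0.884). The smallest p were those of Cdc42ep4 (-0.49), the ligand Wnt7a (-0.61), Atf3, Nt5dc1 (0.79), Plin4 (1.62), Cdc42ep2 (-0.53), Lcp1 (-0.35), Bcorl1 (-0.37) and Slf1 (0.46), each with adjusted p = 0.884. C1ql2 also ranked there at -4.43 (SE 1.22, adjusted p = 0.884), with 21.1 ± 44.4 CPM in sham, of which sham replicate 1 held 98.8 CPM and the next library 2.38. Hippocampal principal neuron genes, C1ql2 among them, stood lower in 14 of 15, with 2 adjusted over the list alone (median -0.57, camera adjusted p = 0.018, and adjusted p = 0.75 with an estimated correlation). The sham contrasts of this region include that library. Glucocorticoid response genes stood higher in 16 of 18, with 1 adjusted over the list alone (median 0.20, camera adjusted p = 0.00012, and adjusted p = 0.69 with an estimated correlation). Striatal genes stood higher in 13 of 13, with 0 adjusted over the list alone (median 0.58, camera adjusted p = 5.8e-06, and adjusted p = 0.75 with an estimated correlation). Choroid plexus genes stood lower in 14 of 16, with 0 adjusted over the list alone (median -0.80, camera adjusted p = 0.02, and adjusted p = 0.75 with an estimated correlation). The microglial gene Aif1 was at -0.53 (SE 0.16, adjusted p = 0.884), and its list was lower in 14 of 16 genes, with 0 adjusted over the list alone (median -0.14, camera adjusted p = 4.4e-05). Its adjusted p was 0.69 with an estimated correlation.

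Excision against sham in the piriform cortex had 0 called genes by edgeR, 1102 at an unadjusted p under 0.05 and 2 called by DESeq2, Col6a4 among them. The heat shock and unfolded protein response list was lower in 17 of 20 genes after excision too, with 0 adjusted over the list alone (median -0.19, camera adjusted p = 0.00036, and adjusted p = 0.63 with an estimated correlation). Between burn and excision its median in this region was 0.00 (camera adjusted p = 0.63), so a fall particular to burn was not shown here. Immediate early genes stood higher in 16 of 17, with 1 adjusted over the list alone (median 0.38, camera adjusted p = 6e-07, and adjusted p = 0.63 with an estimated correlation), and glucocorticoid response genes lower in 15 of 18, with 3 adjusted over the list alone (median -0.26, camera adjusted p = 6.9e-05). An estimated correlation gave an adjusted p of 0.63. Myelin genes were lower in 16 of 16, with 0 adjusted over the list alone (median -0.44, camera adjusted p = 6e-07, and adjusted p = 0.63 with an estimated correlation), with Mbp at 1660 ± 806 CPM in sham and 954 ± 254 CPM in excision (log2 fold change -0.80, SE 0.29, adjusted p = 0.915). Col6a4 had the smallest p (log2 fold change -2.36, SE 0.46, adjusted p = 0.915), followed by Dpysl3, Mapk12, Ky, Mettl27, Rrp8, Anxa11, Slc6a7, Paqr5 and Sfn, each with adjusted p = 0.915.

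**Figure D2:**
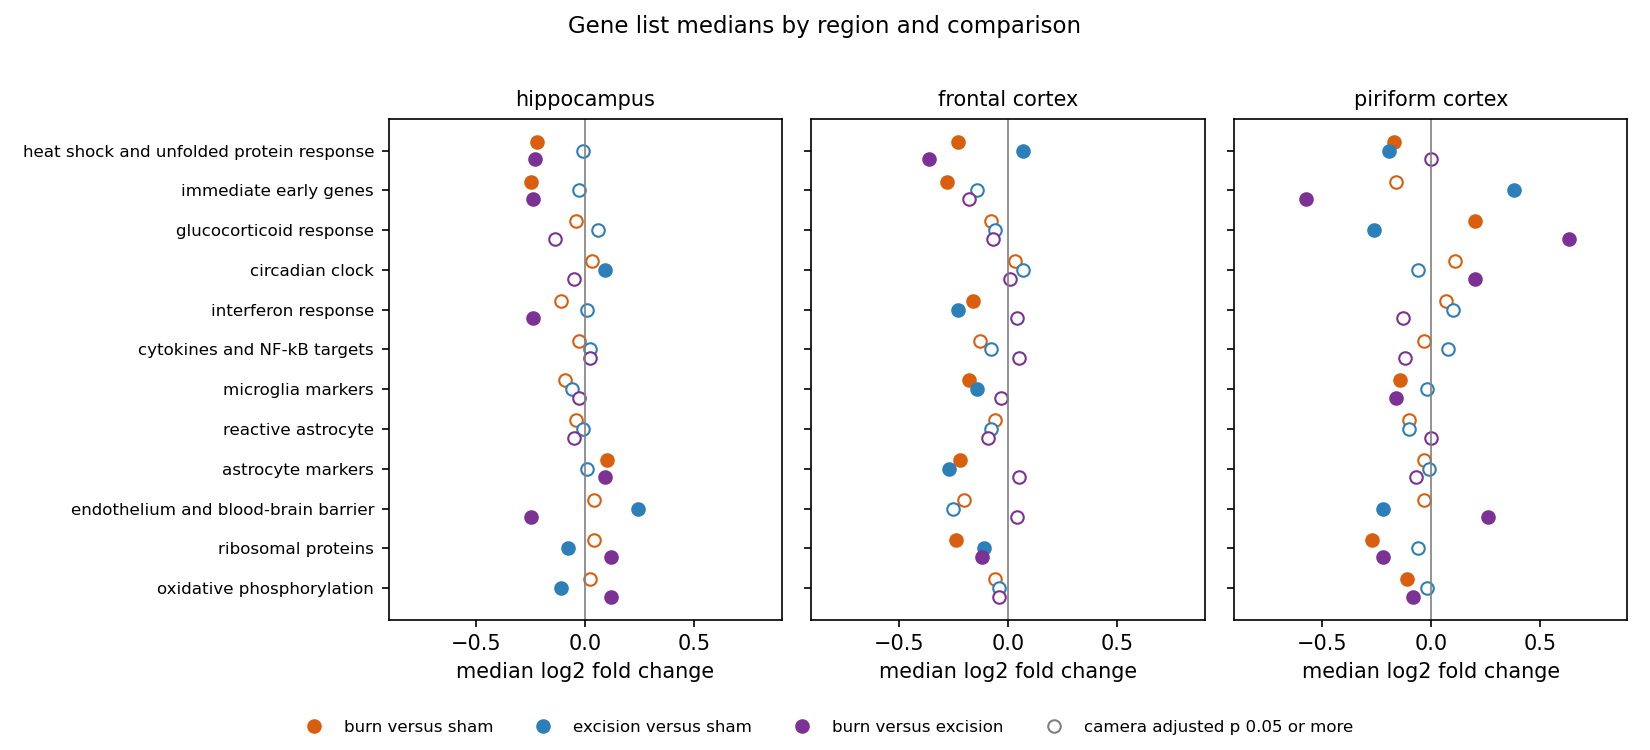
Median log2 fold change (x axis) of 12 gene lists (y axis) in each region and contrast; filled points have a camera adjusted p under 0.05 at the preset correlation, open points do not. The heat shock and unfolded protein response list sat at -0.22 in hippocampus and -0.23 in frontal cortex burn against sham.

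Calls of the hippocampus and frontal cortex overlapped. Burn against sham shared 7 higher genes (Armcx5, Mansc1, Map3k21, Omg, Tox, Wnt9a and Zfp46) where 0.093 would be shared by independent lists, and 7 lower genes (Banp, Creld2, Hspa5, Pdia4, Sdf2l1, Xbp1 and Zbtb40) where 0.19 would. Burn against excision shared 7 lower genes (Banp, Creld2, Mettl3, P4ha1, Sdf2l1, Xbp1 and Zbtb40) where 0.0383 would, and 0 higher genes. Of the 201 hippocampus calls measured in both regions in burn against sham, 182 had the same sign in the frontal cortex. The labels used here do not say whether regions share animals, so the regions are not known to be independent. By the treatment field, hippocampus and frontal cortex libraries of the same batch and library number have the same treatment, so shared animals are possible. The overlap cannot be read as replication in other animals, and the interaction tests held no term for the animal. The burn effect differed between regions by an interaction test at 1 gene between hippocampus and frontal cortex (Ngp, with 1863 at an unadjusted p under 0.05) and at 3 between hippocampus and piriform cortex (Ngp, C1ql2 and Dsp, with 1486). Between frontal and piriform cortex edgeR called 0, with 1160 at an unadjusted p under 0.05. The ER genes were not called in these tests, so their burn effect was not shown to differ between regions.

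Fold changes of the batches, taken as differences of mean log2 CPM within each batch, agreed little across genes. The correlation was 0.197 for hippocampus burn against sham and 0.154 for burn against excision, while it was -0.018 and 0.005 for the same contrasts in the frontal cortex. Excision against sham gave -0.012 in the hippocampus and -0.093 in the frontal cortex. By an interaction test the burn effect differed between hippocampus batches at 9 genes, Dbp among them, with 3180 at an unadjusted p under 0.05. The frontal cortex gave 0 by edgeR, with 4088 at an unadjusted p under 0.05. Burn and excision effects share the sham libraries, and their fold changes correlated at 0.384 in the hippocampus, 0.51 in the frontal cortex and 0.342 in the piriform cortex. Unchanged groups simulated against the shared sham gave 0.521, 0.559 and 0.476. Excision against sham had 0 called genes in each region, so no gene could be called in both contrasts, and shared calls say nothing here.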

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

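Chosen after the result was seen were the tests of the clock score as a covariate and both tests on the lower genes, and the TEC covariate was added after the data were seen, though its test on the ER genes was set before that result.

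The ER chaperone genes called lower in burn were weighed against depth, choroid plexus RNA, TEC share and time of day. The 7 called members in the hippocampus kept a median of -0.54 in the deep batch 2 alone, with 7 called. Their median was -0.41 with the choroid score and -0.46 with the TEC share as covariates, with 7 called each time. These values argue against depth, choroid plexus RNA and TEC share as the whole cause of the fall. The members were chosen as called with the same libraries included, so batch 2 alone is not an independent check. The clock list's median absolute log2 fold change was 0.15 (SE 0.02) against 0.40 for the chaperones in the hippocampus and 0.13 (SE 0.07) against 0.45 in the frontal cortex, which met the bound set against time of day, but that bound was too lenient since Dbp was at 0.56, and at 1.00 in batch 2. In batch 1 Dbp was at 0.02 and -0.10 in the 2 regions while Creld2 was still called (-0.43, adjusted p = 0.0408, and -0.53, adjusted p = 0.0166). The 7 hippocampus members had a median of -0.16 in that batch with 1 called. Other clock genes moved in batch 1, with hippocampus Per1 and Per2 each at -0.28 (adjusted p = 0.248 and 0.234). In burn against excision of batch 1, Per2 was called lower at -0.63 and -0.55 in the 2 regions (adjusted p = 0.0377 and 0.0249). Per1 was called at -0.66 and -0.72, and Creld2 was called lower too, while Dbp was at -0.06 and -0.03. Batch 1 thus does not separate time of day from the burn for Creld2. With a clock score as covariate the median was -0.23 and 1 of 7 was called, as the median SE went from 0.08 to 0.11 and the fold shrank, while in the frontal cortex it was -0.33 with 4 of 5 called. For the ER genes as a group time of day and the burn cannot be told apart, because collection times are not in the labels, and a biological effect of the burn may be present but was not separated from it. Treatments also form runs of library numbers within each batch, so an order of collection or processing cannot be told apart from the burn either.

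The 145 genes called lower in hippocampus burn against sham were weighed against shallow libraries and the share of TEC counts. Without the 4 shallow libraries their median stayed at -0.40 (median SE 0.09) with 119 called, which argues against depth as the whole cause. With the TEC share as covariate the median was -0.31 (median SE 0.09) and 19 were called, while all 145 kept their sign. In batch 2 alone, where the share was 0.07% in burn and 0.0704% in sham, the median was -0.34 with 145 of 145 negative and 18 called, which argues against that share as the whole cause, although the genes were called with these libraries included. In batch 1 the median was -0.46 and the share itself was lower in burn, so for that batch a part played by unspliced RNA and an effect of burn cannot be told apart.

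The higher glucocorticoid response genes in piriform cortex burn against excision (median 0.63, n = 5 and 4) did not rest on a single library, as the lowest median with any burn or excision library left out was 0.54, without excision replicate 1. With the choroid score as covariate the median was 0.64, which argues against choroid plexus RNA as the whole cause. A stress response that differed between the groups at collection may explain it as a hypothesis, but handling was not tested. Time of day stays open, as clock genes stood higher in 12 of 15 in this contrast (median 0.20, camera adjusted p = 0.028, and adjusted p = 0.74 with an estimated correlation). Not tested either was mixing with striatal tissue, whose 13 markers all stood higher in the same contrast (median 0.75) without passing at an estimated correlation (adjusted p = 0.79).

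Single libraries far from the others of their group came up in 22 of 246 groups tested, where chance gives about 1 in 20, or 12. Genes detected were 22137 in hippocampus sham replicate 1 (others 26041 to 28600) and 22242 in burn replicate 5 (others 25514 to 29220), libraries with 7.34 and 7.13 M counts. Mitochondrial counts made up 10.2% of hippocampus burn replicate 9 (others 3.58 to 5.9%), 3.47% of piriform cortex sham replicate 5 (others 8.4 to 10.4%) and 8.95% of piriform cortex burn replicate 2 (others 6.86 to 7.44%). In log2 CPM centred on the batch, the hippocampus held Noxred1 at -0.87 in sham replicate 1 (others 0.24 and above), Fkbp5 at -0.34 in excision replicate 3 (others -0.07 to 0.23), Mbp at -0.72 in excision replicate 8 (others 0.04 to 0.45) and Cldn5 at 0.71 in burn replicate 9 (others -0.71 to -0.03). Among frontal cortex sham libraries, replicate 1 stood apart for Aif1 (0.86), Pak7 (-0.85), Hist1h2bl (1.08) and Hist1h2br (0.93), replicate 2 for Cldn5 (1.44) and replicate 6 for Fkbp5 (-0.62). Frontal cortex excision libraries stood apart for Cldn5 (0.82, replicate 9), Ttr (4.50, replicate 7), Usp43 (-1.90, replicate 10) and Hunk (0.47, replicate 6), and burn libraries for Wnt9a (0.96, replicate 7) and Pak7 (-0.60, replicate 6). Gfap was at -0.88 in piriform cortex excision replicate 3 (others 0.32 to 0.51). The frontal cortex excision replicate 7 and burn replicate 7 are libraries whose labels disagree.

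Differences of the burn effect between regions, by interaction tests, rested on single libraries. Ngp, a neutrophil granule gene, differed by -9.01 (SE 1.7, adjusted p = 0.0336) between hippocampus and frontal cortex and by -9.48 (SE 1.89, adjusted p = 0.0331) between hippocampus and piriform cortex, with 796 counts (39.1 CPM) in hippocampus sham replicate 3 and 0.148 CPM in the next sham library. C1ql2 differed by 4.13 (SE 0.75, adjusted p = 0.00862) and Dsp by 6.08 (SE 1.05, adjusted p = 0.00553) between hippocampus and piriform cortex, with 5670 and 2192 counts in piriform cortex sham replicate 1. That library held 98.8 and 38.2 CPM of them where the next sham libraries held 2.38 and 0.159, and median levels in hippocampus sham were 133 and 31.6 CPM. Whether it holds hippocampal tissue was not tested, and it enters each sham contrast of the piriform cortex.

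Between batches of the hippocampus the burn effect differed for Dbp by -0.98 (adjusted p = 0.00199), Usp2 by -0.54 (adjusted p = 0.0107), Zfp362 by -0.42 (adjusted p = 0.0382), Tbx2 by -1.73 (adjusted p = 0.0176) and Ccna2 by -2.14 (adjusted p = 0.00773). It also differed for Cd160 by -1.82 (adjusted p = 0.0498), Gm42849 by -2.61 (adjusted p = 0.0279), 9530062K07Rik by -1.61 (adjusted p = 0.00881) and Lncppara by -2.46 (adjusted p = 0.00388), each by an interaction test in edgeR as batch 1 minus batch 2.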

How the results depend on the processing

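The TEC covariate and the hippocampus without libraries under 10 M counts were chosen after the data were seen. Of 8372 values of named genes under alternatives, 7235 kept their side of the threshold, 1118 lost the call, 19 gained it and 0 reversed. Of 1560 list values 1366 kept their side, 126 lost the call, 62 gained it and 6 reversed. Reversals were counted only for genes and lists called in the reported fit, and uncalled ones could not lose a call. Sign changes of uncalled genes were thus not counted, such as Fos in hippocampus burn against sham (-0.40, and 0.23 in batch 1 alone). DESeq2 size factors left every count within 1.5 times the reported one. Counts below are given for burn against sham, then burn against excision, unless stated, with genes shared with the reported calls in brackets, and the cause of a move was not tested unless stated. Hippocampus (202 and 41): no count filter 123 (112) and 21 (19), DESeq2 629 (202) and 303 (39), 2 surrogate variables 83 (49) and 18 (12), no batch term 106 and 8, batch 1 alone 1324 (124) and 197 (12), batch 2 alone 31 (23) and 0, TEC covariate 30 (26) and 19 (15). A replicate block gave 21 (18), and leaving out the libraries under 10 M counts 3, for burn against excision. Excision against sham had 2 calls with no filter and 1 in batch 2 alone. Frontal cortex (59 and 44): no count filter 24 and 12, DESeq2 328 (57) and 175 (42), 2 surrogate variables 288 (55) and 173 (43), replicate block 0 and 8, batch 1 alone 1328 (47) and 1318 (38), batch 2 alone 0 and 0, disagreeing labels left out 32 (29) and 15 (15), titles 0 and 1. Burn against sham gave 26 with no batch term and 153 (59) with the TEC covariate. Each 0 is by edgeR, with 1446 genes at an unadjusted p under 0.05 in the hippocampus, and in the frontal cortex 2176 for the replicate block, 1178 and 490 for batch 2 and 2098 for titles. Batches alone hold fewer libraries (3 sham in frontal cortex batch 2). Piriform cortex burn against excision gave 1 with no filter, 1 with a replicate block, 1 with titles and 59 by DESeq2, which called 1 in burn against sham and 2 in excision against sham. Without the libraries whose labels disagree, the batch interaction of the frontal cortex gave 4 and the frontal minus piriform interaction 1. In genes above the median of mean CPM, batch agreement was 0.113 for hippocampus excision against sham, -0.186 for frontal cortex burn against sham and 0.03 for frontal cortex excision against sham, and without disagreeing labels it was -0.128 for frontal cortex burn against sham and -0.106 for burn against excision. List medians reversed for immediate early genes in the hippocampus (0.05 in burn against sham, batch 1 alone, and 0.17 in burn against excision, batch 2 alone). In the frontal cortex they reversed for ribosomal proteins (0.12 in burn against sham and 0.15 in excision against sham, batch 2 alone), glutamatergic genes (-0.07 in burn against sham, batch 2 alone) and striatal genes (-0.50 in excision against sham, batch 1 alone).

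Leaving out each library in turn gave 50 to 745 calls in hippocampus burn against sham, 9 to 326 in burn against excision, 19 to 206 in frontal cortex burn against sham, 10 to 284 in burn against excision and 0 to 3 in piriform cortex burn against excision. Excision against sham in the 3 regions and piriform cortex burn against sham gave 0 to 0 by edgeR. Hippocampus burn against sham moved by over 1.5 times without burn replicates 2 (81), 3 (55), 4 (58), 5 (67), 8 (745) and 9 (116), and sham replicates 1 (443), 2 (60), 3 (107), 4 (82), 5 (50), 7 (70), 8 (100) and 9 (517). Burn against excision did so without burn 1 (161), 2 (24), 3 (23), 4 (16), 5 (20), 6 (21), 7 (15), 8 (326), 9 (20) and 10 (21), excision 1 (19), 2 (70), 3 (27), 4 (12), 5 (9), 6 (141), 7 (22), 8 (27) and 9 (20), and sham 2 (25), 5 (23) and 8 (27). In the frontal cortex burn against sham moved without burn 1 (31), 2 (38), 3 (24), 4 (24), 6 (206), 7 (28) and 8 (109), excision 3 (38) and 10 (107), and sham 1 (36), 2 (26), 5 (34), 7 (27) and 8 (19). Burn against excision moved without burn 1 (19), 2 (29), 3 (10), 4 (10), 6 (284) and 7 (24), and excision 2 (22), 3 (13), 4 (29), 6 (89), 7 (29), 8 (29), 9 (24) and 10 (70). Piriform cortex burn against excision moved without burn 1 (1) and sham 5 (3). Named genes kept their call in 697 of 899 such fits in hippocampus burn against sham and 530 of 728 in the frontal cortex. Replicate numbers did not pair samples within a region, as libraries of the same number in different groups correlated at a mean of 0.027, 0.007 and 0.038 in hippocampus, frontal and piriform cortex.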

Other observations

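The comparison of C1ql2, Dsp and neutrophil genes by library was made after their values were seen, and the splits were planned.

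Cytokine, reactive astrocyte and complement lists were not called by camera in burn against sham in any region. Other immune lists were called as lower: interferon genes (median -0.16, adjusted p = 0.021) and microglial genes (median -0.18, adjusted p = 0.001) in the frontal cortex, and microglial (median -0.14, adjusted p = 4.4e-05) and activated microglial genes (median -0.19, adjusted p = 0.0043) in the piriform cortex. Their adjusted p was 0.67, 0.62, 0.69 and 0.75 in that order with an estimated correlation. In the frontal cortex interferon and microglial genes were lower in excision against sham too (medians -0.23 and -0.14, adjusted p = 0.039 and 0.00073, and 0.91 and 0.48 with an estimated correlation) and near 0 between burn and excision (medians 0.04 and -0.03, adjusted p = 0.69 each). These frontal cortex shifts were not shown to be particular to burn, and the contrasts share the sham libraries. In the piriform cortex microglial genes were lower in burn against excision too, as given above, but did not pass with an estimated correlation. Activated microglial genes went the other way in hippocampus burn against excision, higher in 15 of 17 with 0 called (median 0.10). Their camera adjusted p was 0.042, and 0.71 with an estimated correlation, while interferon genes stood lower in that contrast, as given above. Cytokine and NF-kB targets had medians of -0.03 in the hippocampus (adjusted p = 0.68), -0.13 in the frontal cortex (adjusted p = 0.17) and -0.03 in the piriform cortex (adjusted p = 0.45). Reactive astrocyte genes were at -0.04 (adjusted p = 0.38), -0.06 (adjusted p = 0.21) and -0.10 (adjusted p = 0.44), and complement genes at -0.04, -0.06 and -0.02 (adjusted p = 0.80, 0.78 and 0.83). Ribosomal protein genes stood lower in 28 of 28 in piriform cortex burn against sham (median -0.27, camera adjusted p = 1.1e-12) and in frontal cortex burn against sham (median -0.24, camera adjusted p = 4e-06), where the median reversed to 0.12 in batch 2 alone. With an estimated correlation their adjusted p was 0.70 and 0.67.

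Other genes of neutrophils were high in the same hippocampus library as Ngp, with S100a9 at 85.4 CPM, Camp at 36.1 CPM and S100a8 at 34.2 CPM in sham replicate 3. Libraries of the same number in hippocampus and frontal cortex correlated at a mean of 0.074 over 27 pairs, against -0.018 over 108 pairs of other numbers.

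Other splits of the same samples into groups of the same sizes were fitted as the real ones, 100 for each contrast with the real split included. The splits argue against chance for the calls of hippocampus burn against sham, where 1 split, the real one, gave as many (202, highest other 1). They cannot separate treatment from the order of library numbers, because each treatment forms a run of numbers within its batch. For burn against excision there, 2 splits did (41, highest other 297). Counts as high were also rare for frontal cortex burn against sham (3 splits, real 59, highest other 2281) and burn against excision (2 splits, real 44, highest other 2574). The batch interaction of the hippocampus had 2 such splits (real 9, highest other 65). Each of these shares lay under the preset 0.05, without adjustment over the contrasts. In each case but the first another split called more genes than the real one, so chance is not excluded for those. What the few splits that called several times the real count have in common was not tested. Where the real count was 0 by edgeR, 100 of 100 splits give as many whatever the data hold, so the splits say nothing on chance: excision against sham in the hippocampus (highest other 3), frontal cortex (303) and piriform cortex (726), burn against sham and burn against excision in the piriform cortex (1 and 36), and the batch interaction of the frontal cortex (3). Unadjusted p under 0.05 were held by 727, 1007, 1102, 896, 1658 and 4088 genes in that order. For region interactions 50 splits were fitted, and chance is not excluded for hippocampus minus frontal cortex (3 splits; 1, highest other 1) or hippocampus minus piriform cortex (16 splits; 3, highest other 17). Frontal minus piriform cortex had a real count of 0 by edgeR, with 1160 at an unadjusted p under 0.05, so its 50 of 50 splits (highest other 127) say nothing either.

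Batch agreement did not exceed that of other splits in any contrast, and chance is not excluded for it. In the hippocampus burn against sham gave 0.197 (23 of 100 splits as high, highest other 0.427), excision against sham -0.012 (50 splits, 0.516) and burn against excision 0.154 (25 splits, 0.428). In the frontal cortex the values were -0.018 (55 splits, 0.611), -0.093 (71 splits, 0.569) and 0.005 (53 splits, 0.523) in the same order.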
